A study of Mus musculus with 20 samples.

How the data were processed

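RNA was measured in 16 libraries of sorted satellite cells labelled NEMO KO, with 4 biological replicates each at days 0, 2, 4 and 7 after injury, and open chromatin in 4 libraries of day 2, with 2 biological replicates each of wild type and NEMO KO. Per the labels' protocols, at least 10000 cells were sorted per library, about 10.0 ng of RNA went into SmartSeq4 cDNA libraries, and 76-bp read pairs were sequenced on a HiSeq 2500 while ATAC libraries were sequenced as 76-bp pairs on a NextSeq. The labels put days 0 and 2 on one lane and days 4 and 7 on another. They give 3 second index sequences: 1 was used for day 0 and day 2 replicate 1, 1 for day 2 replicates 2 to 4 and day 4 replicates 1 and 2, and 1 for day 4 replicates 3 and 4 and day 7.

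The submitters' processing notes name STAR 2.5.0a, RSEM, cutadapt, Bowtie2, MACS2 and bedtools, and the builds mm10 and mm9 without their roles. The deposited RNA values are RSEM expected counts per Ensembl gene, per the file headers, which are estimates that need not be whole, and RSEM FPKM, which the authors scaled by transcript length and mapped fragments. Whether counting used strand is not given in the sources used here, and RSEM splits reads shared between near-identical genes, so values of paralogs are uncertain. The gene tables hold 49671 genes with a symbol for each, and isoform tables were not used. The deposited ATAC files hold aligned tags and MACS2 peaks, and per the labels' file names the authors trimmed reads, split pairs into single tags, removed duplicates, shifted tags for Tn5, called peaks at p 0.01 and filtered them by overlap. In each deposited peak list the fold enrichment over background is a ratio and the −log10 q-value is that of the authors' peak caller, and both were used only to filter or describe peaks within a list. The ATAC coordinates fit the chromosome lengths of mm9, and the filtered list of NEMO KO replicate 1 differs in format from the others, with scores not capped and random contigs kept. Where both mates span a short fragment, plus tags start 4.0 bp after and end 5.0 bp after the minus tags (medians), the offsets of the Tn5 shift, so 5′ ends were used as deposited. The number of columns of sample values left unused in these tables was 0.

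The expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by day (minimum count 10.0, minimum total 15.0), which left 17517 genes, and libraries were scaled by TMM. A quasi-likelihood model with a term per day was fitted to all 16 libraries, so that they share an estimate of the spread, and 5 contrasts were tested: days 2, 4 and 7 against 0, 4 against 2 and 7 against 4. The any-day result is the F test over the 3 day coefficients. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM were computed from the scaled library sizes. The median log2 fold change of all genes was -0.13, -0.09, -0.12, 0.04 and -0.26 in the 5 contrasts in that order, and -0.34, -0.31, -0.21, 0.04 and -0.13 with DESeq2-type size factors, so the direction of small changes depends on the scaling.

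Before the data were examined, 24 gene lists with 386 entries were fixed, of which 385 were found in the tables and 370 tested. The 16 lists of programs cover quiescence, immediate early and stress genes, myogenic commitment, sarcomere, DNA replication, mitosis, NF-κB components, NF-κB targets, interferon response, cell death, p53 and senescence, oxidative phosphorylation, glycolysis, ribosome assembly, extracellular matrix and chromatin regulators. The other 8 are markers of cells the sort could hold, of myeloid, neutrophil, lymphoid, endothelial, fibroadipogenic, mural, Schwann and erythroid kinds. At day 4, 9 of 11 fibroadipogenic and 10 of 16 myeloid markers were at a mean of 5 CPM or more. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 120 tests of list and contrast. Of 53 calls, 5 held with an estimated correlation: mitosis and replication for day 2 against 0 and day 7 against 0, and sarcomere for day 4 against 2. Counts of members are given over all genes tested and adjusted over the list alone.

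The genes named follow a rule fixed at the same time: in each contrast the 5 largest rises and 5 largest falls among genes past the threshold with no overlap between the 4 and 4 libraries, a mean of at least 20.0 CPM in the higher group and a symbol that is not a predicted model, in addition 12 fixed genes, and from each list up to 4 members of smallest adjusted p. From these the text prints mainly genes whose call held in every alternative, and says where a named call did not. A few genes that the rule takes are not reported here. Genes without a count in a group are given as bounds against 3 counts over the group, which cover counting error only. For ATAC peaks, the rule takes the 5 largest rises and falls among called peaks that separate the libraries and lie above the median CPM.

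For ATAC, the filtered peak lists were merged with bedtools 2.31.1 into 142590 regions, and 71540 found in at least 2 libraries were kept, of which 70013 passed filterByExpr. Tn5 insertions were counted in them with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3), scaled by TMM over peaks and tested by genotype in edgeR. Overlap of peak lists counted peaks sharing at least 1 bp.

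In data simulated from the fit to all 16 libraries, 200.0 of 16707 genes, drawn above a floor of mean CPM, were changed in the day 2 libraries. For day 2 against 0 the fit recovered 14% of 2-fold and 71% of 4-fold changes and called 0 other genes (edgeR). In simulated ATAC data (67572 peaks), 83% of 4-fold and 96% of 8-fold changes were recovered, with 4 other peaks called. Peaks below the median CPM were not assessed alone. In a simulated list test 1 list of 20.0 genes raised 1.5-fold was called (adjusted p = 4.2e-10) and 0 of the unchanged lists were. No 2 libraries agreed within sampling noise, with a chi-square per degree of freedom of at least 15.0 between libraries of a day, and Spearman correlations within a day ran from 0.884 to 0.981.

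Alternatives were DESeq2 1.42.0, DESeq2-type size factors in edgeR, no filter on low counts, a CPM of at least 1 in at least 4 libraries, limma on log2(FPKM + 1), the replicate number as a block, the second index as a covariate, only the 8 libraries of a contrast, each replicate left out, fry and an estimated correlation for lists, and for ATAC other scalings, peak sets, chromosomes and counting. Chosen after seeing the data, and left out in further fits, were the 4 libraries highest in other cells' markers and, separately, 5 libraries with Gm8210 under 1 CPM. Figures were drawn with matplotlib 3.10.9.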

Results

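Satellite cells, the stem cells of skeletal muscle, were taken from mice whose genotype label is a knockout of NEMO (gene symbol Ikbkg), the regulatory subunit of the IKK kinase that activates NF-κB. RNA was sequenced from 16 libraries of sorted cells, 4 biological replicates each before injury (day 0) and 2, 4 and 7 days after a tibial injury, and all 16 carry the label NEMO KO. Accessible chromatin was profiled by ATAC-seq, which maps where the Tn5 transposase can insert, in 4 libraries of day 2, of which 2 are labelled wild type and 2 NEMO KO. No wild-type RNA library was among the data used here, so the RNA comparisons are between days within the libraries labelled NEMO KO and the genotypes are compared by ATAC-seq alone. RNA library totals ran from 7192194 to 23222060 expected counts, with 17985 to 27638 genes holding a count. ATAC libraries held 14687260 and 23356172 deposited tags for wild type and 16892518 and 14412248 for NEMO KO. Values of genes are CPM, expected counts scaled to the same library total, mean ± SD of n = 4, and log2 fold changes are the later minus the earlier day ± SE, with adjusted p from edgeR.

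Ikbkg (ENSMUSG00000004221), the targeted gene, was counted in every RNA library. Its CPM at day 0 were 41.4, 24.7, 38.9 and 25.2 in replicates 1 to 4, and at day 2 they were 11.2, 32.1, 7.18 and 34.0. At day 4 they were 12.1, 14.1, 49.0 and 79.1, and at day 7 they were 34.3, 14.6, 47.5 and 17.2. Ikbkg passed in none of the 5 contrasts tested, with adjusted p of 0.42 for day 2 against 0, 0.78 for day 4 against 0, 0.85 for day 7 against 0, 0.32 for day 4 against 2 and 0.62 for day 7 against 4. At days 2, 4 and 7 the highest values were in day 2 replicates 2 and 4, day 4 replicates 3 and 4 and day 7 replicate 3, the libraries in which the predicted gene Gm8210, chosen after its values were seen, was under 1 CPM. Which part of the gene was deleted is not given in the sources used here, and with no wild-type RNA neither the deletion nor the genotype label of any single library could be checked from these values.

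Markers of other cell types were present in every library and varied within days. Summed over the fixed marker lists, day 0 replicates 1 and 3 held 26632 and 20721 CPM against 6287 and 6364 in replicates 2 and 4, mostly from genes of fibroadipogenic progenitors, the connective tissue precursors of muscle. At day 2, replicates 2 and 4 held 26850 and 31933 CPM against 2961 and 3183 in replicates 1 and 3, mostly from myeloid genes, which summed to 17043 and 24552 CPM in those libraries and to 937.6 and 754.0 CPM in the others. The sums of days 4 and 7 lay between 3002 and 6601 CPM. The 10 most abundant genes of a library took 12.55% to 18.8% of its counts at day 0, 4.09% and 4.73% in day 2 replicates 1 and 3, 10.98% and 10.66% in day 2 replicates 2 and 4, 4.85% to 9.45% at day 4 and 6.61% to 7.00% at day 7. Mitochondrial genes took 4.36% to 5.64% at day 0, 1.73% and 1.87% in day 2 replicates 1 and 3, 7.63% and 5.13% in replicates 2 and 4, 2.20% to 5.56% at day 4 and 1.96% to 2.29% at day 7.

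Over the 4 days, 9725 of 17517 tested genes differed. Their highest mean fell on day 2 for 3213 genes (33.0%), on day 0 for 2911 (29.9%), on day 4 for 2702 (27.8%) and on day 7 for 899 (9.24%). The design text of the series places the largest response at day 2. Against day 0, 6951 genes passed at day 2, 6044 at day 4 and 3291 at day 7, and the differences between these counts were not tested.

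**Figure D1:**
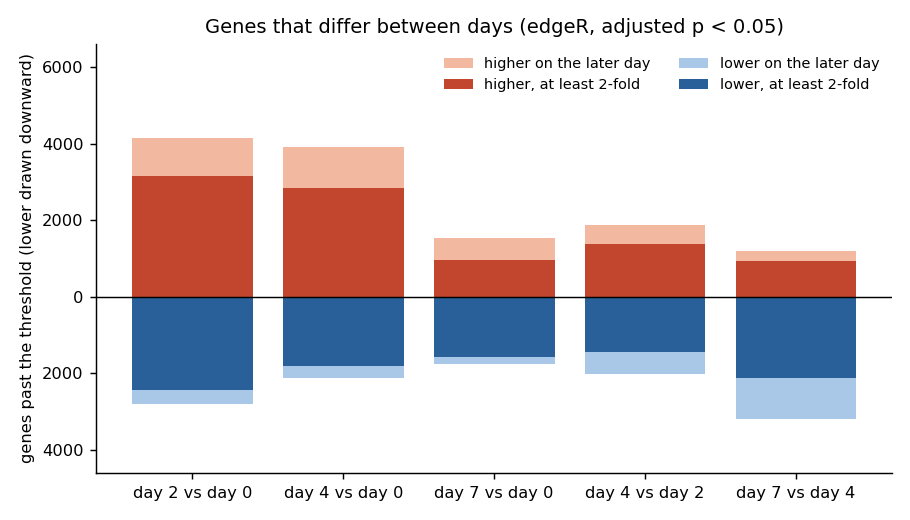
Number of genes past the threshold (adjusted p under 0.05) in each comparison of days, higher bars upward and lower bars downward, with the part of each bar at least 2-fold changed in the darker shade. Against day 0 the genes higher number 4147 at day 2, 3917 at day 4 and 1545 at day 7.

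The comparison of day 2 with day 0 asks what the cells express as they leave the resting state after injury. Genes of cell division rose. All 20 mitosis genes and all 20 DNA replication genes of the fixed lists rose. One was Cdk1 from 6.48 ± 1.51 to 266 ± 40.6 CPM (log2 fold change 5.36 ± 0.28, adjusted p = 5.3e-09), the kinase that drives entry into mitosis. Mcm5, a subunit of the replicative helicase, rose from 18.9 ± 4.58 to 527 ± 43.8 CPM (log2 fold change 4.80 ± 0.25, adjusted p = 5.3e-09). Genes of the resting state and of immediate early and stress responses fell, 15 of 18 and 16 of 18 respectively. Both lists lost their call with an estimated correlation (adjusted p = 0.14 and 0.073 with it). The share of counts in the 10 most abundant genes, at most 10.98% in a day 2 library, was lower too, and so was the mitochondrial share of replicates 1 and 3. Myod1, the transcription factor of activated myoblasts, rose from 75.3 ± 35.7 to 479.9 ± 263 CPM (log2 fold change 2.67 ± 0.38, adjusted p = 4.3e-05). Pax7, the transcription factor that marks satellite cells, fell from 54.0 ± 18.3 to 9.43 ± 6.11 CPM (-2.51 ± 0.46, adjusted p = 4.1e-04).

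In the cell division lists, further examples were Cdc20 (5.09 ± 0.27), Ube2c (4.98 ± 0.32) and Birc5 (5.34 ± 0.37) for mitosis and Mcm2 (4.99 ± 0.31), Tyms (3.33 ± 0.22) and Pcna (3.06 ± 0.21) for replication, each with its log2 fold change. The proliferation marker Mki67 rose from 13.3 ± 4.82 to 144 ± 93.5 CPM (adjusted p = 1.2e-04) and the G1 cyclin Ccnd1 from 57.4 ± 20.4 to 207 ± 78.0 CPM (adjusted p = 6.8e-04). The median log2 fold change was 4.89 over the mitosis list (camera, adjusted p = 1.8e-35, and adjusted p = 0.046 with an estimated correlation) and 4.17 over the replication list (adjusted p = 4.7e-31, and adjusted p = 0.036 with an estimated correlation). Adjusted over the list alone, the same numbers rose, 20 and 20.

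Of 17 glycolysis genes 12 rose and 2 fell (adjusted p = 7.5e-11, and adjusted p = 0.052 with an estimated correlation). Examples were Pgk1 (2.98 ± 0.17), Pgam1 (2.87 ± 0.16) and Ldha, which makes lactate, from 408 ± 28.2 to 3431 ± 781 CPM (log2 fold change 3.07 ± 0.23, adjusted p = 6.4e-08). Of 20 genes of oxidative phosphorylation 19 rose and none fell (adjusted p = 2.7e-10, and adjusted p = 0.12 with an estimated correlation), among them Cox5a (2.43 ± 0.16) and Cycs (2.61 ± 0.21), cytochrome c. Of 20 genes of ribosome assembly 19 rose (adjusted p = 7.5e-11, and adjusted p = 0.14 with an estimated correlation), with Nhp2 (2.73 ± 0.23), Wdr12 (1.97 ± 0.23), Bop1 (1.87 ± 0.21) and Pes1 (1.47 ± 0.17). The counts adjusted over the list alone were equal, 12 and 2, 19, and 19.

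Among immediate early and stress genes, Btg2, an antiproliferative gene, fell from 3522 ± 798 to 151 ± 38.0 CPM (log2 fold change -4.55 ± 0.31, adjusted p = 3.3e-08). Falls were also seen in Fosb (-4.39 ± 0.32), Jund (-3.66 ± 0.29) and Junb (-3.52 ± 0.30), subunits of the AP-1 transcription factor. The list as a whole was lower (adjusted p = 6.8e-21), and 17 fell when adjusted over the list alone. In the quiescence list 15 of 18 fell, 15 also adjusted over the list alone (adjusted p = 8.6e-10). Among them were Chrdl2 (-4.50 ± 0.39), Gas1 (-3.29 ± 0.29), Spry1 (-3.01 ± 0.33), an inhibitor of growth factor signalling, and Hes1, a Notch target, from 229.8 ± 73.6 to 25.5 ± 9.65 CPM (-3.17 ± 0.35, adjusted p = 2.8e-06). The cell cycle inhibitor Cdkn1c stood at 127 ± 42.6 and 102 ± 36.7 CPM (adjusted p = 0.52).

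Of 14 myogenic genes 5 rose and 2 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.48). Those that rose included Myog, which drives differentiation, from 70.7 ± 30.7 to 268 ± 136 CPM (1.92 ± 0.42, adjusted p = 0.0017), Chrna1 (2.38 ± 0.36), an acetylcholine receptor subunit, and Gm7325, known as myomixer and needed for myoblast fusion, which stayed low at 5.23 CPM (5.02 ± 0.82). Of 21 sarcomere genes 2 rose and 5 fell (also over the list alone; adjusted p = 0.10), the falls including Acta1 (-1.85 ± 0.51) and Tnnt1 (-2.01 ± 0.38). Of 20 extracellular matrix genes none rose and 5 fell, 5 over the list alone (adjusted p = 0.073), with the basement membrane collagens Col4a1 (-1.67 ± 0.26) and Col4a2 (-1.28 ± 0.31).

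Of 16 myeloid markers 13 rose, and 16 adjusted over the list alone (adjusted p = 2.5e-04, and adjusted p = 0.70 with an estimated correlation). Among them were Cd68 from 1.29 ± 1.27 to 518 ± 624 CPM (log2 fold change 8.83 ± 1.32, adjusted p = 6.1e-05) and Cd14 (5.39 ± 0.84). The largest rises by the fixed rule were of Hk3, Lat2 and Cd300c2, known from white blood cells, with log2 fold changes of 10.44 ± 1.72, 10.32 ± 1.62 and 10.23 ± 1.68. Of 25 NF-κB target genes 11 rose and 2 fell, 11 and 3 over the list alone, without a call for the list (adjusted p = 0.11): Csf1 (2.60 ± 0.31), Sod2 (1.01 ± 0.16) and Il1b (7.93 ± 1.25) rose and Nfkbiz (-2.49 ± 0.38) fell. Nfkbia stood at 267 ± 154 and 379.7 ± 282 CPM (adjusted p = 0.41) and Tnfaip3 at 135 ± 136 and 148 ± 104 CPM (adjusted p = 0.89). Ccl2, a chemokine of monocytes, rose from 33.8 ± 38.4 to 235 ± 227 CPM (adjusted p = 0.032). SDs were wide, with most myeloid counts in day 2 replicates 2 and 4. Without these and day 0 replicates 1 and 3, Cd68, Cd14, Hk3, Lat2, Cd300c2, Csf1, Sod2 and Il1b passed. NF-κB targets were called up (adjusted p = 0.0043). Myeloid sums still differed (937.6 and 754 CPM, 24.7 and 36.7 at day 0), so myeloid RNA is not excluded.

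The 5 largest falls included Krt76, a keratin, from 104 ± 47.4 to 0.251 ± 0.375 CPM (log2 fold change -8.55 ± 0.99, adjusted p = 5.1e-06), Mmd2 (-6.28 ± 0.93) and Kcnt1 (-6.21 ± 0.91), a potassium channel gene. Markers of cells other than myeloid moved less. Of 8 mural cell genes 3 fell (4 over the list alone), of 7 Schwann cell genes 3 (3), of 11 fibroadipogenic genes 1 rose and 2 fell (0 and 2), of 5 erythroid genes 1 fell (0), of 4 lymphoid genes 1 fell (1) and of 11 endothelial and 4 neutrophil genes none passed. These lists were not called, with adjusted p from 0.077 to 0.66, and the endothelial median and mean were above 0 (0.57 and 0.27) where camera pointed down. Examples were Abcc9 (-3.58 ± 0.70) of mural cells, Pmp22 (-1.80 ± 0.32) of Schwann cells, and Dpt (-2.09 ± 0.48) and Gsn (-2.01 ± 0.37) of fibroadipogenic cells.

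In all, 4147 genes were higher and 2804 lower at day 2, of which 3162 and 2434 at least 2-fold, and 35.7% of genes had no overlap between the 2 sets of 4 libraries against 2.86% by chance. With DESeq2-type size factors the split was 3427 and 3540, with DESeq2 itself 3734 and 4313, and on log2(FPKM + 1) 3388 and 4295, and with the second index of the labels as a covariate 2570 and 939. In that last fit Pax7 no longer passed, and Ccl2 lost its call without day 0 replicate 2 or 4 or day 2 replicate 2 or 4.

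The comparison of day 4 with day 0 asks what the cells express 4 days after injury. Of 14 myogenic genes 8 rose, and of 21 sarcomere genes 9 rose and 1 fell. Both lists were called up and lost the call with an estimated correlation (adjusted p = 0.26 and 0.14 with it). Myog rose from 70.7 ± 30.7 to 1228 ± 429 CPM (log2 fold change 4.12 ± 0.46, adjusted p = 8.5e-06). The acetylcholine receptor subunits Chrng and Chrnd and the slow troponin Tnni1 were among the 5 largest rises by the fixed rule. The cell cycle inhibitor Cdkn1c rose from 127 ± 42.6 to 1044 ± 494 CPM (log2 fold change 3.04 ± 0.41, adjusted p = 3.6e-05). Cell division genes were still above day 0, 18 of 20 in each of both lists, and immediate early genes were still below it, 16 of 18. None of these 3 list calls held with an estimated correlation (adjusted p = 0.12 for mitosis, 0.12 for replication and 0.078 for immediate early genes). The share of the 10 most abundant genes was also below day 0, at 9.45% or less in each day 4 library.

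In the myogenic list none fell, and 8 rose also over the list alone (adjusted p = 1.4e-04). Examples were the muscle intermediate filament gene Des (2.07 ± 0.25), Gm7325 (7.67 ± 0.86) and Tmem8c, known as myomaker and needed for fusion, from 13.1 ± 7.21 to 107 ± 26.4 CPM (log2 fold change 3.03 ± 0.37, adjusted p = 1.8e-05). Myod1 was at 237 ± 42.9 CPM (1.65 ± 0.37, adjusted p = 0.0024). In the sarcomere list 10 rose and 1 fell over the list alone (adjusted p = 0.0017), with Tnni1 (5.76 ± 0.57), Myl4 (4.06 ± 0.45), Tnnt2 (4.26 ± 0.47) and Tnnt1 (3.04 ± 0.38). The largest rises by the rule were of R3hdml, without a count at day 0 and at least 431 times higher at day 4 against a floor of 3 counts over the 4 libraries, Chrng (6.42 ± 0.45), Chrnd (5.83 ± 0.56), Tnni1 and Upp1 (5.72 ± 0.40), uridine phosphorylase.

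Of 20 genes of oxidative phosphorylation 19 rose, 19 over the list alone (adjusted p = 9.0e-17, and adjusted p = 0.061 with an estimated correlation). Among them were Atp5o from 90.3 ± 8.30 to 583 ± 206 CPM (log2 fold change 2.69 ± 0.27, adjusted p = 3.1e-06) and Cox5a (1.95 ± 0.16). Of 17 glycolysis genes 11 rose and none fell, 11 over the list alone (adjusted p = 6.8e-09, and adjusted p = 0.068 with an estimated correlation). Among them were the muscle enolase Eno3 (3.81 ± 0.41) and Pgk1 (2.60 ± 0.16). Ribosome assembly genes were closer to day 0, with 4 of 20 higher (4 over the list alone; adjusted p = 0.25). In mitosis 18 rose over the list alone (adjusted p = 3.0e-17). An example was Cdk1 (3.29 ± 0.25). In replication 18 rose over the list alone (adjusted p = 7.8e-13), with Mcm2 (3.07 ± 0.29) and Uhrf1 (3.74 ± 0.44). Mki67, at 26.5 ± 19.7 CPM, did not pass (adjusted p = 0.15), nor did Ccnd1 at 59.8 ± 30.2 CPM (adjusted p = 0.92).

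In the immediate early and stress list 16 fell over the list alone (adjusted p = 2.9e-16). Examples were Zfp36, which destabilises inflammatory mRNAs, from 4529 ± 1124 to 506 ± 194 CPM (log2 fold change -3.16 ± 0.31, adjusted p = 2.8e-06) and Fosb (-3.48 ± 0.31). Of 18 quiescence genes 8 fell and 2 rose, likewise over the list alone (adjusted p = 4.4e-04, and adjusted p = 0.56 with an estimated correlation, and adjusted p = 0.17 with the second index as a covariate): Cd34 (-2.91 ± 0.21), Chrdl2 (-3.74 ± 0.38) and Gas1 (-2.64 ± 0.28) fell and Cdkn1c, which is on this list, rose. Pax7 was at 28.3 ± 9.46 CPM (adjusted p = 0.11) and Myf5 at 269 ± 93.9 CPM (adjusted p = 0.89). Of 25 NF-κB targets 7 fell and none rose, 7 over the list alone, without a call for the list (adjusted p = 0.27, and 0.0054, a call, with the second index as a covariate). Nfkbiz fell from 418 ± 78.8 to 44.1 ± 15.1 CPM (-3.24 ± 0.39, adjusted p = 1.6e-05) and the chemokine Cxcl1 from 563 ± 306 to 85.7 ± 36.7 CPM (adjusted p = 0.0031). Nfkbia and Ccl2 did not pass (adjusted p = 0.27 and 0.22).

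Of the 8 lists of other cells' markers, 4 were called lower than at day 0. Of 7 Schwann cell genes 6 fell (7 over the list alone; adjusted p = 0.0022, and adjusted p = 0.56 with an estimated correlation), among them Pmp22 (-2.27 ± 0.32). Of 8 mural genes 6 fell (6; adjusted p = 0.017, and adjusted p = 0.70 with an estimated correlation), with Myh11 (-5.29 ± 1.18). Of 11 fibroadipogenic genes 6 fell (6; adjusted p = 0.025, and adjusted p = 0.74 with an estimated correlation), with Dpt (-2.72 ± 0.49) and Gsn (-1.65 ± 0.37), and of 11 endothelial genes 4 fell (4; adjusted p = 0.018, and adjusted p = 0.74 with an estimated correlation). These lists move with day 0 replicates 1 and 3, whose marker sums were the highest of their day. Without the 4 libraries highest in other cells' markers, the fibroadipogenic, mural and endothelial calls ended (adjusted p = 0.59, 0.32 and 0.077) and the Schwann call stayed (adjusted p = 0.0055). Without calls were the erythroid (4 of 5 fell, 5 over the list alone, adjusted p = 0.095) and lymphoid lists (0 of 4, adjusted p = 0.46), and, pointing up, the myeloid (1 of 16 rose, 0 over the list alone, median log2 fold change 1.39, adjusted p = 0.51) and neutrophil lists (0 of 4, median 1.54, adjusted p = 0.91). The myeloid list was called up without those 4 libraries (adjusted p = 0.0055) and down with the second index as a covariate (adjusted p = 0.0041). Of single libraries, leaving out day 4 replicate 2 ended the endothelial, mural and fibroadipogenic calls (adjusted p = 0.059, 0.055 and 0.083), and leaving out day 0 replicate 1 or 3 the fibroadipogenic call (0.083 and 0.051). Of 20 matrix genes 6 fell and 1 rose (likewise over the list alone; adjusted p = 0.30), with Col4a1 (-1.54 ± 0.26) lower and Lamb1 (1.19 ± 0.21), a laminin chain, higher. The largest falls by the rule included Ncmap, a myelin gene, from 50.1 ± 53.3 to 0.432 ± 0.384 CPM (log2 fold change -6.78 ± 1.44, adjusted p = 0.0016).

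At day 4, 3917 genes were higher and 2127 lower than at day 0, of which 2851 and 1811 at least 2-fold, with no overlap in 33.5% of genes. The split was 3159 and 2848 with DESeq2-type size factors, 3485 and 3518 with DESeq2, 3440 and 3057 on log2(FPKM + 1) and 795 and 306 with the second index as a covariate, where R3hdml no longer passed. Days 0 and 4 were run on different lanes, so lane and day cannot be told apart.

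The comparison of day 7 with day 0 asks how far expression is from the resting state after a week. Cell division genes were again higher, with 20 of 20 mitosis genes and 18 of 20 replication genes up. Of 14 myogenic genes 5 rose, such as Myog from 70.7 ± 30.7 to 1097 ± 113 CPM (log2 fold change 3.96 ± 0.46, adjusted p = 2.7e-05), and of 21 sarcomere genes 9 rose, with list calls that were lost with an estimated correlation (adjusted p = 0.14 and 0.061 with it). Of 18 immediate early genes 13 were below day 0 (adjusted p = 0.12 with an estimated correlation), and the 10 most abundant genes took 7.00% of counts or less in each day 7 library. Mki67 rose from 13.3 ± 4.82 to 187 ± 45.7 CPM (log2 fold change 3.81 ± 0.56, adjusted p = 2.5e-04), a higher mean than at day 2.

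Over the mitosis list the median log2 fold change was 3.90 (20 rose over the list alone; adjusted p = 1.9e-62, and adjusted p = 0.016 with an estimated correlation), with Cdk1 (4.11 ± 0.26), Ube2c (3.96 ± 0.30) and Ccnb1 (4.08 ± 0.37). Over the replication list it was 2.55 (19 over the list alone; adjusted p = 1.0e-32, and adjusted p = 0.034 with an estimated correlation), with Mcm2 (3.53 ± 0.29), Mcm6 (2.79 ± 0.31) and Uhrf1 (4.24 ± 0.45). Cep55, which acts in the last step of cell division, was among the 5 largest rises by the rule, from 0.849 ± 0.403 to 26.8 ± 7.66 CPM (4.92 ± 0.50, adjusted p = 9.8e-06). The large falls included Mmd2 (-7.33 ± 0.99), Mpzl2 (-6.81 ± 1.01) and Krt76 (-6.35 ± 0.89).

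In the myogenic list none fell, and over the list alone 5 rose (adjusted p = 4.4e-06): Myog, Gm7325 (7.43 ± 0.85), Tmem8c (3.29 ± 0.38), Myod1 (1.91 ± 0.37) and Chrna1 (1.90 ± 0.35). In the sarcomere list none fell, and 10 rose over the list alone (adjusted p = 3.5e-06). Among them were the cardiac actin gene Actc1 from 56.7 ± 29.3 to 584 ± 192 CPM (log2 fold change 3.37 ± 0.46, adjusted p = 1.3e-04), Tnni1 (5.22 ± 0.56) and Tnnt2 (4.19 ± 0.47). Of 20 matrix genes 4 rose and 1 fell, likewise over the list alone (adjusted p = 1.2e-04, and adjusted p = 0.56 with an estimated correlation), with Lamb1 (1.61 ± 0.22), Col5a2 (1.18 ± 0.20) and Col5a1 (1.53 ± 0.33) higher. Of 18 quiescence genes 1 rose and 4 fell, 3 and 5 over the list alone, without a call (adjusted p = 0.065), where Cdkn1c rose (2.91 ± 0.41), Cd34 (-1.83 ± 0.20), Sdc4 (-1.98 ± 0.28) and Chrdl2 (-2.01 ± 0.35) fell, and Pax7, at 41.9 ± 16.4 CPM, did not pass (adjusted p = 0.60).

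In the immediate early and stress list 16 fell over the list alone (adjusted p = 1.0e-13), with Btg2 (-2.37 ± 0.28), Zfp36 (-2.47 ± 0.30) and Junb (-2.28 ± 0.29). Of 20 genes of oxidative phosphorylation 5 rose (5; adjusted p = 6.0e-04, and adjusted p = 0.54 with an estimated correlation). Of 17 glycolysis genes 5 rose and 3 fell (6 and 3; adjusted p = 0.16), with Pgk1 (1.38 ± 0.16) higher. None of 20 ribosome assembly genes passed (0; adjusted p = 0.065). Of 25 NF-κB targets 5 fell and none rose (5; adjusted p = 0.20, and 0.0074, a call, with the second index as a covariate). Among them were Nfkbiz (-2.66 ± 0.38) and Cxcl1 (-2.71 ± 0.63), while Nfkbia, Tnfaip3 and Ccl2 did not pass (adjusted p = 0.093, 0.077 and 0.16). Among other cells' markers, 5 of 5 erythroid genes fell (5; adjusted p = 0.015, and adjusted p = 0.56 with an estimated correlation). So did 5 of 7 Schwann genes (7; adjusted p = 0.0067, and adjusted p = 0.60 with an estimated correlation) and 3 of 8 mural genes (6; adjusted p = 0.025, and adjusted p = 0.71 with an estimated correlation). The Schwann and mural calls ended without the 4 libraries highest in other cells' markers (adjusted p = 0.26 and 0.71), as did that of Pmp22 (-1.35 ± 0.31), while the myeloid and fibroadipogenic lists were called up there (adjusted p = 4.1e-05 and 0.019). With the second index as a covariate both were called down (adjusted p = 0.0016 and 1.6e-04). The mural call also ended without day 0 replicate 1 or 3 (adjusted p = 0.083 and 0.074). In the fibroadipogenic list 1 of 11 fell (1), and no gene of the endothelial (11), myeloid (16), neutrophil (4) or lymphoid (4) lists passed. These lists were not called, with adjusted p from 0.11 to 0.96, and the neutrophil median and mean were above 0 (2.83 and 2.08) where camera pointed down.

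In all, 1545 genes were higher and 1746 lower at day 7, of which 960 and 1584 at least 2-fold, with no overlap in 30.8% of genes, and DESeq2 gave 1655 and 2974. The count of lower genes was 864 without day 0 replicate 1, 891 without day 0 replicate 3, and 875, 677, 840 and 862 without day 7 replicates 1, 2, 3 and 4. With the second index as a covariate the counts were 217 higher and 51 lower. Mki67, Myog, Gm7325, Cep55, Lamb1, Pgk1, Cxcl1 and the cell division genes named here kept their calls there and the other genes named lost theirs. In that fit the matrix list pointed down (adjusted p = 0.66), and the sarcomere, oxidative phosphorylation and erythroid lists lost their calls (adjusted p = 0.059, 0.57 and 0.06). Days 0 and 7 were run on different lanes, so lane and day cannot be told apart.

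From day 2 to day 4, 19 of 20 mitosis and 19 of 20 replication genes fell (adjusted p = 0.068 and 0.051 with an estimated correlation). Over the same step 13 of 21 sarcomere genes and 8 of 14 myogenic genes rose (adjusted p = 0.016 and 0.16 with an estimated correlation). Myog rose from 268 ± 136 to 1228 ± 429 CPM (log2 fold change 2.20 ± 0.42, adjusted p = 0.0017) and Cdkn1c from 102 ± 36.7 to 1044 ± 494 CPM (3.36 ± 0.41, adjusted p = 6.8e-05). Mki67 fell from 144 ± 93.5 to 26.5 ± 19.7 CPM (-2.43 ± 0.53, adjusted p = 0.0039). All 16 myeloid markers fell (adjusted p = 0.54 with an estimated correlation).

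In the cell division lists (19 and 20 fell over the lists alone; adjusted p = 2.6e-23 for mitosis and 1.3e-21 for replication), examples were Cdk1 (-2.07 ± 0.24), Aurka (-2.44 ± 0.34) and Pcna (-1.85 ± 0.20). Ccnd1 fell from 207 ± 78.0 to 59.8 ± 30.2 CPM (adjusted p = 0.0024). Of 20 ribosome assembly genes 17 fell, 19 over the list alone (adjusted p = 2.8e-15, and adjusted p = 0.12 with an estimated correlation). Among these were Ncl, nucleolin, from 1645 ± 784 to 333 ± 139 CPM (log2 fold change -2.30 ± 0.35, adjusted p = 3.2e-04), Dkc1 (-2.20 ± 0.26) and Nolc1 (-1.92 ± 0.29). Of 17 glycolysis genes 3 fell and 1 rose, likewise over the list alone (adjusted p = 0.023, and adjusted p = 0.56 with an estimated correlation): Pgam1 (-1.43 ± 0.15) and Ldha (-1.07 ± 0.21) fell and Pfkm (1.23 ± 0.27), the muscle phosphofructokinase, rose, and the list was not called without the 4 libraries highest in other cells' markers (adjusted p = 0.077), nor without day 2 replicate 4 or day 4 replicate 2 (0.092 and 0.086). Of 20 genes of oxidative phosphorylation 6 rose and 2 fell (7 and 2; adjusted p = 0.18), with Cycs (-1.31 ± 0.20) lower.

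Among muscle genes, 14 sarcomere genes rose over the list alone (adjusted p = 1.2e-11). Likewise, 8 myogenic genes rose and 1 fell over the list alone (adjusted p = 8.7e-05). Tnnt1 rose from 3.04 ± 0.555 to 101 ± 52.5 CPM (log2 fold change 5.05 ± 0.42, adjusted p = 5.6e-06). Further rises were of Myl4 (3.90 ± 0.44), Tnni1 (3.91 ± 0.51), Cdh15 (3.15 ± 0.37), the M-cadherin gene, Rapsn (1.94 ± 0.29) and Tmem8c (2.22 ± 0.36). Of 18 quiescence genes 11 rose and 1 fell, 12 and 2 over the list alone (adjusted p = 1.6e-05, and adjusted p = 0.36 with an estimated correlation). Those that rose included the Notch targets Hes1 (3.06 ± 0.35) and Heyl, from 133 ± 68.6 to 1261 ± 275 CPM (3.25 ± 0.41, adjusted p = 7.6e-05). Of this list Cd34 (-2.38 ± 0.20) fell. Of 18 immediate early and stress genes 9 rose, 11 with 1 lower over the list alone (adjusted p = 6.0e-05, and adjusted p = 0.56 with an estimated correlation). Examples were Ier2 (1.93 ± 0.23), Btg2 (1.95 ± 0.28) and Nr4a1 (1.70 ± 0.32). The largest rises by the rule were of R3hdml (7.61 ± 0.99), the homeobox gene Dbx1 (6.17 ± 0.87), Dcx (5.98 ± 0.77), Cited1 (5.38 ± 0.72) and Kif26b (5.10 ± 0.78). Of 20 matrix genes 4 rose and 1 fell (likewise over the list alone; adjusted p = 0.21), with Lamb1 (1.35 ± 0.21) higher, and the list was called up without the 4 libraries highest in other cells' markers (adjusted p = 7.9e-06).

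In the myeloid list (16 fell over the list alone; adjusted p = 2.3e-07) examples were Cd14 (-6.25 ± 0.88), Cd68 (-6.45 ± 1.16) and Itgam (-6.86 ± 1.52). Of 25 NF-κB targets 11 fell and none rose, 14 and 1 over the list alone (adjusted p = 2.2e-05, and adjusted p = 0.56 with an estimated correlation). Tnf fell from 84.1 ± 79.3 to 0.388 ± 0.402 CPM (log2 fold change -7.57 ± 1.37, adjusted p = 0.0012) and Ccl2 from 235 ± 227 to 11.2 ± 9.24 CPM (-4.39 ± 1.06, adjusted p = 0.0076). The largest falls by the rule were of Cd200r1, without a count at day 4 and at least 382 times lower there against a floor of 3 counts over the 4 libraries, Hk3 (-10.57 ± 1.72), F7 (-9.74 ± 1.58), Nckap1l (-8.77 ± 1.49) and the cytokine gene Il1a (-7.92 ± 1.83). These genes move with day 2 replicates 2 and 4, which held the highest myeloid sums, and Il1a lost its call, and the endothelial list pointed up (adjusted p = 0.45), without the 4 libraries highest in other cells' markers. Among other markers 3 of 11 endothelial genes fell (8 over the list alone; adjusted p = 0.025, and adjusted p = 0.74 with an estimated correlation, and 0.19, 0.10 and 0.08 without day 2 replicate 2, day 2 replicate 4 or day 4 replicate 2) and 2 of 11 fibroadipogenic genes (2; adjusted p = 0.13). None of the mural (8), Schwann (7, of which 4 fell over the list alone), erythroid (5), neutrophil (4) or lymphoid (4) genes passed, with adjusted p of the lists from 0.12 to 0.70.

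At day 4, 1864 genes were higher and 2022 lower than at day 2, of which 1376 and 1448 at least 2-fold, with no overlap in 19.0% of genes. The counts were 1216 and 1310 without day 4 replicate 4, 2818 and 2733 without the 4 libraries highest in other cells' markers, a set chosen after seeing the data. They were 761 and 699 with the second index as a covariate, where Mki67 and Ccnd1 no longer passed. Days 2 and 4 were run on different lanes, so lane and day cannot be told apart.

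From day 4 to day 7, 18 of 20 genes of oxidative phosphorylation and 11 of 17 glycolysis genes fell (adjusted p = 0.073 and 0.051 with an estimated correlation). Over the same step, 9 of 20 matrix genes and 12 of 20 mitosis genes rose and none of either list fell (adjusted p = 0.33 and 0.27 with an estimated correlation). Markers of fibroadipogenic progenitors, cells that make collagen, pointed up in the same step (median log2 fold change 2.00, adjusted p = 0.0078, and adjusted p = 0.72 with an estimated correlation), and without the 4 libraries highest in other cells' markers the adjusted p was 1.2e-04. Col3a1, a fibrillar collagen gene, rose from 3328 ± 666 to 11083 ± 2811 CPM (log2 fold change 1.74 ± 0.23, adjusted p = 7.2e-04), and Top2a, the topoisomerase of dividing cells, from 50.5 ± 30.7 to 277 ± 57.0 CPM (2.45 ± 0.42, adjusted p = 0.0014). Uqcrc1, a subunit of respiratory complex III, fell from 1352 ± 490.2 to 317 ± 53.3 CPM (-2.09 ± 0.29, adjusted p = 7.5e-04). Myog stood at 1228 ± 429 and 1097 ± 113 CPM and did not pass (adjusted p = 0.80).

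In oxidative phosphorylation 18 fell over the list alone (adjusted p = 4.1e-14). In glycolysis 14 fell over the list alone (adjusted p = 1.9e-10), with Tpi1 (-1.82 ± 0.26), Pkm (-1.42 ± 0.20) and Pgk1 (-1.22 ± 0.16). In the matrix list 10 rose over the list alone (adjusted p = 3.9e-08), among them Col4a1 (2.00 ± 0.27), Lamc1 (1.65 ± 0.28) and Col4a2 (1.69 ± 0.32). The largest rises by the rule were of Col15a1, a basement membrane collagen, from 2.289 ± 1.598 to 48.4 ± 19.1 CPM (log2 fold change 4.38 ± 0.59, adjusted p = 7.2e-04), the long noncoding RNA Meg3 (3.61 ± 0.75), Ptprz1 (3.36 ± 0.56), the kinetochore gene Knl1 (3.11 ± 0.64) and Atad5 (3.01 ± 0.65). The largest falls by the rule were of Cited1 (-4.58 ± 0.69), Msln (-4.49 ± 0.88), R3hdml (-4.18 ± 0.81), Lgals3 (-3.45 ± 0.74) and osteopontin, Spp1, from 744 ± 786 to 76.0 ± 11.7 CPM (-3.29 ± 0.94, adjusted p = 0.019).

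In the mitosis list 12 rose over the list alone (adjusted p = 2.7e-10). Among them were Aurkb (2.48 ± 0.39), Nusap1 (1.99 ± 0.39) and Mki67 (2.82 ± 0.53, adjusted p = 0.0021). In the replication list 2 of 20 rose, none over the list alone (adjusted p = 0.021, and adjusted p = 0.72 with an estimated correlation), and the list was not called without day 4 replicate 4 or day 7 replicate 2 (adjusted p = 0.088 and 0.06). Of 14 myogenic genes 1 rose and 3 fell (1 and 4; adjusted p = 0.62), with Des (-1.53 ± 0.24), Cdh15 (-2.01 ± 0.36) and Rapsn (-1.37 ± 0.28) lower. Of 21 sarcomere genes 1 rose and 4 fell (1 and 4; adjusted p = 0.81). Of 18 quiescence genes 5 rose and 1 fell (8 and 1; adjusted p = 0.0038, and adjusted p = 0.61 with an estimated correlation). Examples were Gas1 from 208 ± 61.1 to 560.1 ± 87.3 CPM (log2 fold change 1.43 ± 0.27, adjusted p = 0.0021), Cd34 (1.07 ± 0.20) and Tenm4 (1.77 ± 0.44). Of 18 immediate early and stress genes 6 rose (6; adjusted p = 1.7e-04, and adjusted p = 0.56 with an estimated correlation), with Fosb (1.35 ± 0.28) and Jun (1.50 ± 0.39).

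Of 20 ribosome assembly genes 3 fell (3; adjusted p = 0.74). None of 25 NF-κB targets passed (0; adjusted p = 0.80). Among other cells' markers 1 of 11 fibroadipogenic genes rose (0 over the list alone; list adjusted p = 0.066 with the second index as a covariate and 0.055 without day 4 replicate 2), Dpt (1.55 ± 0.47), and 1 of 8 mural, Abcc9 (1.91 ± 0.66), and 1 of 7 Schwann genes, Pmp22 (0.92 ± 0.31), rose (0 and 0 over the lists alone), each losing its call without several single replicates. None of the endothelial (11), myeloid (16), erythroid (5), neutrophil (4) or lymphoid (4) genes passed, with adjusted p of these lists from 0.065 to 0.93. The camera direction was opposite to the sign of both median and mean in the sarcomere (median -0.14), NF-κB target (-0.09), myeloid (-0.40) and neutrophil (1.98) lists. In the ribosome assembly list median and mean differed in sign (0.08 and -0.02).

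At day 7, 1186 genes were higher and 3192 lower than at day 4, of which 926 and 2111 at least 2-fold, with no overlap in 32.7% of genes. With DESeq2-type size factors, which change the scaling alone, the split was 1530 and 2568. With DESeq2 it was 2080 and 3344 and with limma on log2(FPKM + 1) 2307 and 1728, where the test changes too. It was 208 and 260 without day 4 replicates 3 and 4, day 7 replicate 3 and day 2 replicates 2 and 4, a set chosen after seeing the data. Without single replicates the higher genes numbered 458, 1791, 591 and 613 for day 4 replicates 1 to 4 and 673, 646, 661 and 643 for day 7 replicates 1 to 4, and the lower genes 2048 without day 4 replicate 1. Spp1 lost its call without day 4 replicate 3 or day 7 replicate 2 or 4.

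**Figure D2:**
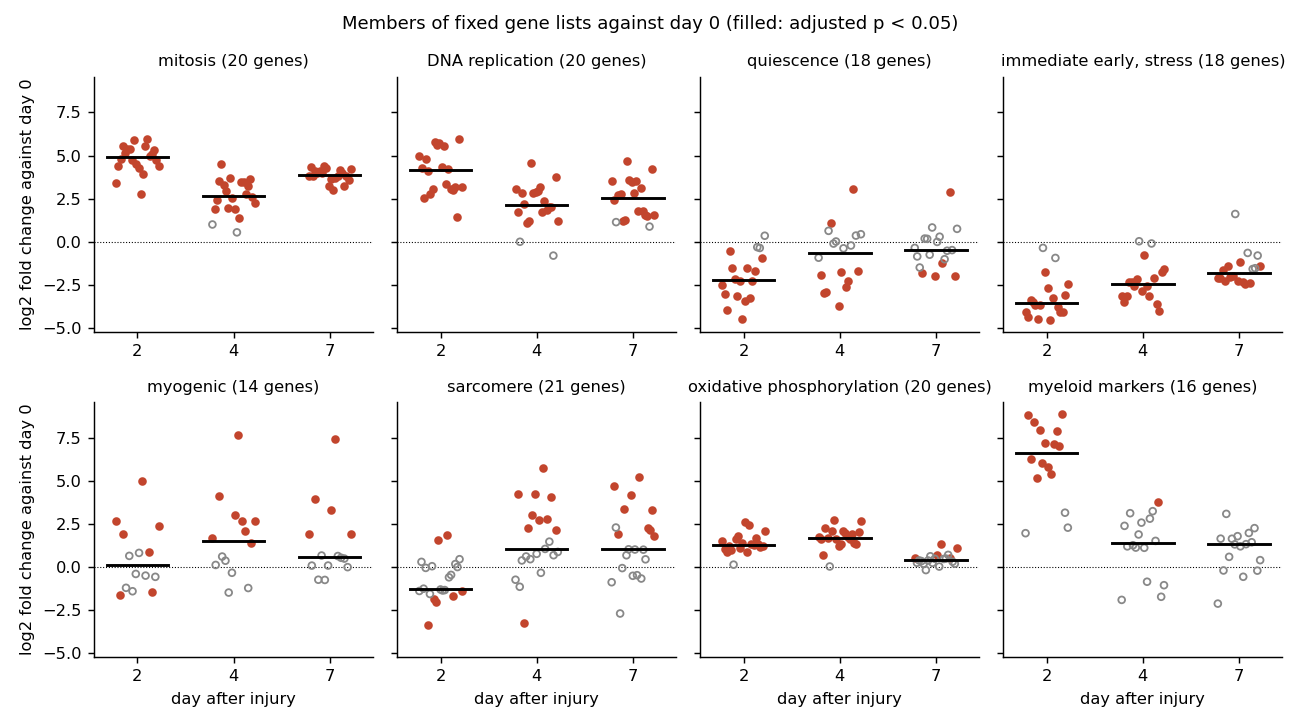
Log2 fold change against day 0 (vertical axis) of each tested member of 8 fixed gene lists at days 2, 4 and 7 (horizontal axis), with filled points for members past the threshold, open points for the others and a bar at the median. The mitosis median is 4.89 at day 2, 2.68 at day 4 and 3.90 at day 7, and the immediate early median lies below 0 on each day.

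**Figure D3:**
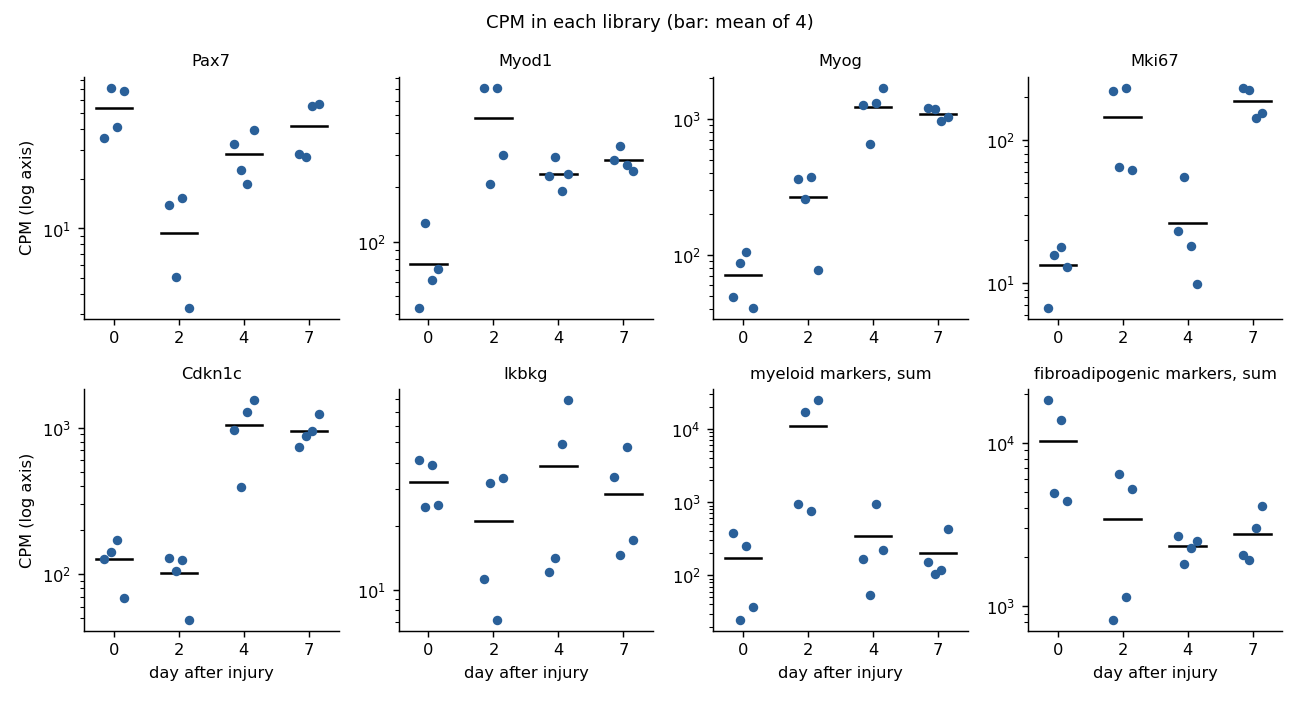
CPM per library (log axis) of Pax7, Myod1, Myog, Mki67, Cdkn1c and Ikbkg and of the summed myeloid and fibroadipogenic markers at days 0, 2, 4 and 7, with a bar at the mean of 4 libraries. Myog has means of 70.7, 268, 1228 and 1097 CPM, and 2 of the 4 day 2 libraries hold myeloid sums of 17043 and 24552 CPM.

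The ATAC comparison asks where chromatin differs between NEMO KO and wild-type satellite cells 2 days after injury, and rests on 2 libraries of each genotype. Of 70013 consensus peaks tested, 12 were called more accessible in NEMO KO and 19 less. The share of changes found under 4-fold or in weaker peaks was not assessed. Of the 31, 12 lay on chromosome 9, 5 each on 6 and 18 and 3 on 17. Values below are Tn5 insertions in peaks scaled to the same library total (CPM), mean ± SD of n = 2, with positions in mm9, the build whose chromosome lengths the files fit.

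Peaks were named by the fixed rule, which takes called peaks above the median of tested peaks (7.36 CPM). Among these the largest rise was at chromosome 6, 33594242 to 33594883, from 1.13 ± 1.04 CPM in wild type to 15.4 ± 4.37 CPM in NEMO KO (log2 fold change 3.39 ± 0.52, edgeR adjusted p = 4.3e-04). The peak at chromosome 4, 118036383 to 118037182, rose from 5.17 ± 1.63 to 35.8 ± 7.33 CPM (2.91 ± 0.35, adjusted p = 1.1e-06). The other large rises were at chromosome 18, 13210776 to 13211863 (log2 fold change 2.99), chromosome 9, 105604355 to 105605000 (2.87), and chromosome 11, 114826702 to 114827249 (2.82). The 3 called peaks that rose and lay below that median had larger changes and were named after their values were seen. At chromosome 18, 11497107 to 11497577, and chromosome 6, 136852423 to 136852757, both wild-type libraries held 0 CPM and NEMO KO 9.93 ± 0.709 and 7.14 ± 3.43 CPM. At chromosome 9, 94785342 to 94785867, the values were 0.488 ± 0.426 and 9.07 ± 0.222 CPM (4.69).

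The largest fall was at chromosome 9, 115457021 to 115457775, from 23.4 ± 4.65 CPM in wild type to 0.410 ± 0.580 CPM in NEMO KO (log2 fold change -5.75 ± 0.59, adjusted p = 2.7e-08). The fall with the smallest adjusted p among those named was at chromosome 19, 57477848 to 57478983, from 86.0 ± 6.01 to 6.34 ± 0.262 CPM (-3.76 ± 0.29, adjusted p = 1.8e-12). Further falls were at chromosome 9, 88494156 to 88494734 (-4.15), chromosome 17, 74508726 to 74509197 (-3.26), and chromosome 9, 63951503 to 63952592 (-3.10). Below the median, 3 called peaks fell by more than the last of these, the largest at chromosome 9, 105782993 to 105783533 (-4.34), also named after its values were seen. No mm9 annotation was used here, so these peaks carry no gene names.

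**Figure D4:**
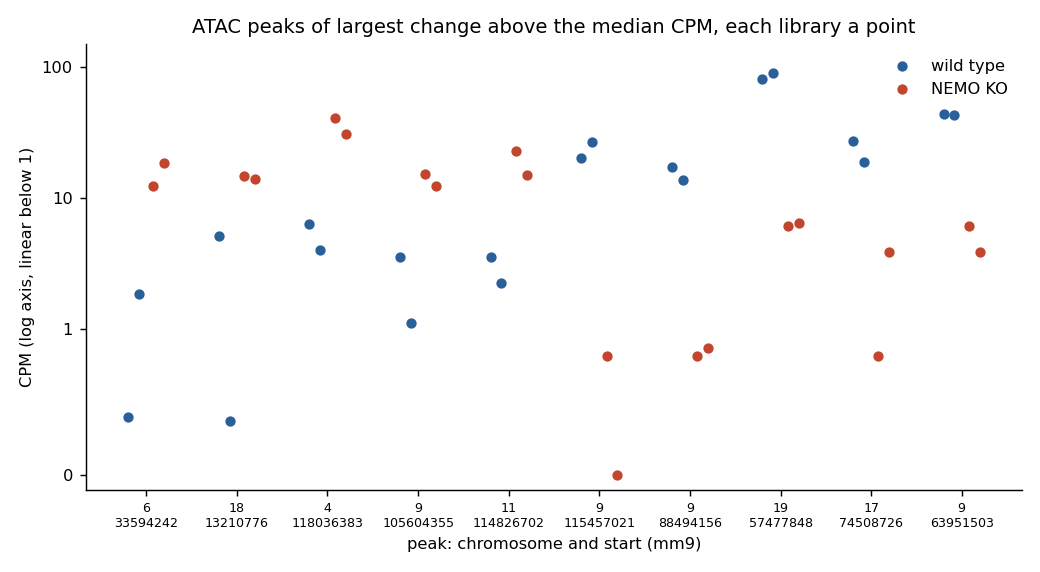
Insertions (CPM, log axis, linear below 1) in each of the 4 ATAC libraries for the 10 peaks that the fixed rule names, the 5 largest rises and 5 largest falls in NEMO KO among called peaks above the median of 7.36 CPM, named by chromosome and mm9 start. The 2 libraries of each genotype lie apart from those of the other in every peak shown, which the rule for naming required.

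The calls depended on scaling and on single libraries, with 1 higher and 0 lower peaks when scaled by all deposited tags (65 and 81 at unadjusted p under 0.05). There were none either way with TMM over 10 kb bins (18 and 41 at unadjusted p under 0.05), 9 and 12 with DESeq2, and 101 and 94 without wild-type replicate 2. They were 33 and 23 without wild-type replicate 1, 4 and 14 without NEMO KO replicate 1 and 4 and 9 without NEMO KO replicate 2. Wild-type replicate 2 held 45.2% of its insertions in consensus peaks against 17.8% in wild-type replicate 1 and 28.7% and 31.96% in NEMO KO replicates 1 and 2. Peak lists of the same genotype shared 60.3% ± 12.8 of their peaks (4 directed pairs) and lists of different genotypes 62.2% ± 11.9 (8 directed pairs), a difference smaller than the spread between pairs. Without wild-type replicate 2 the order turned, to 65.9% ± 6.03 within (2 pairs) and 54.5% ± 8.33 between genotypes (4 pairs). The lists held 59510 and 93089 peaks for wild type and 81846 and 71041 for NEMO KO.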

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

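The tests of RNA from other cells by the ratio of myeloid markers and of the splits of the libraries were written before their results were seen, and the test of library size and the count of lists with their smallest p in the real split were chosen after. Within each day, 25 measures were compared, the 12 fixed genes, the marker sums and library statistics, which made 100 groups of 4 libraries, and 5 values stood apart from the other 3 libraries of their day, about the 1 in 20 that chance gives.

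Day 7 replicate 4 held a myeloid sum of 424 CPM against 105 to 149.9 in the other libraries of day 7, and a neutrophil sum of 117 CPM against at most 0.3. Day 4 replicate 2 held a mural sum of 919 CPM against 2200.0 to 2375, and its sum over all markers was 3002 CPM against 5434 to 5720. Day 0 replicate 1 held an erythroid sum of 1501 CPM against 113 to 119, a list whose hemoglobin genes are near-identical copies, so that their single values are uncertain.

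Beyond these single libraries, markers of other cell types were high in 2 of the 4 libraries of day 0 and of day 2, as given in the report. All 16 myeloid markers were higher in both such libraries of day 2 than in the other 2, and 10 of 11 fibroadipogenic markers in both such libraries of day 0. Library size stays open: these libraries had the smallest totals of their day and at least 835 more genes with a count, which other cells can add. RNA from other cells may be the source, as cells of another type bring all their transcripts, and the SD of the log2 ratio between both high libraries of day 2 over the myeloid markers was 0.57, against a median of 0.536 and a 5th percentile of 0.391 for lists of matched CPM (percentile 62.7). That value lay above the bound set for excluding this source by less than the spread of matched lists, and the bound assumed the same mix of white blood cells in separate animals, so the source stays open; no biological explanation was tested.

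Fits to the 8 libraries of a contrast alone were repeated over all splits of those libraries. For day 2 against 0 the real split of the 8 libraries gave 5332 genes and the highest other 101, for day 4 against 0 it gave 5797 against 0, for day 7 against 0 4440 against 2, for day 4 against 2 2006 against 11 and for day 7 against 4 5055 against 2, each the largest of 35 splits (1 of 35). Over all days, 9725 genes stood against 337 at most in the other groupings (1 of 100), so chance can be excluded for these counts. The highest other split of days 2 and 0 set day 2 replicates 1 and 3 with day 0 replicates 2 and 4 against the 4 libraries high in other cells' markers. For the number of lists called by camera it cannot be excluded: 26 of 35 splits gave as many as the real 8 for day 2 against 0 (highest other 18), 10 as many as 13 for day 4 against 0 (17), 12 as many as 13 for day 7 against 0 (17), 15 as many as 11 for day 4 against 2 (18) and 16 as many as 10 for day 7 against 4 (17). Taken list by list, the real split gave the smallest p of the 35 splits for 22 of the 53 called lists, where chance gives 3.34 over the 117 list tests compared. For the other 31 calls, splits with as small a p, the real one included, numbered 2 of 35 for quiescence, 5 for ribosome assembly and 14 for myeloid markers at day 2. At day 4 against 0 they numbered 2 for sarcomere, 3 for replication, 4 for mitosis, 4 for quiescence and 10 to 16 for endothelial, Schwann, mural and fibroadipogenic markers. At day 7 against 0 they numbered 3 for oxidative phosphorylation, 5 for sarcomere, 5 for cell death, 12 for matrix, 12 for interferon genes and 15 to 18 for mural, Schwann and erythroid markers. For day 4 against 2 they numbered 4 for quiescence, 7 for glycolysis, 8 for immediate early genes, 12 for NF-κB targets, 11 for myeloid and 17 for endothelial markers. From day 4 to 7 they numbered 5 for matrix, 6 for quiescence, 7 for mitosis, 12 for immediate early genes, 16 for replication and 11 for fibroadipogenic markers, so chance cannot be excluded for these calls taken singly.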

How the results depend on the processing

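The libraries highest in other cells' markers, the 5 with Gm8210 under 1 CPM, and for lists and peak overlap the single replicates, were left out only after the data were seen. The other alternatives were set before.

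Counts of genes moved with DESeq2 and limma (other test and scaling), the second index and single libraries. DESeq2-type size factors, which change scaling alone, left each within 1.5 times. DESeq2 gave 4313 lower genes for day 2 against 0, 3518 for day 4 against 0 and 2974 for day 7 against 0, and 2080 higher for day 7 against 4. Limma on log2(FPKM + 1) gave 4295 lower for day 2 against 0, 2397 higher for day 7 against 0, and 2307 higher and 1728 lower for day 7 against 4, which had 1595 lower without the filter on low counts. With the second index as a covariate the higher and lower genes were 2570 and 939 for day 2 against 0, 795 and 306 for day 4 against 0, 217 and 51 for day 7 against 0, and 761 and 699 for day 4 against 2; the index nearly follows the days, so fewer libraries inform the contrast. With only the 8 libraries of a contrast, 2365 were higher for day 7 against 0, 903 higher and 1103 lower for day 4 against 2, and 2348 higher for day 7 against 4. Without the 4 libraries high in other cells' markers, 1141 were lower for day 7 against 0, and 2818 higher for day 4 against 2 and 2794 for day 7 against 4. Without the 5 libraries with Gm8210 under 1 CPM, a setting run for counts of genes and of called lists only, 1191 were higher and 1273 lower for day 4 against 2 and 208 and 260 for day 7 against 4, with fewer libraries in the fit. The cause of the other moves was not tested.

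Leaving out each replicate in turn, day 2 against 0 held 3447 to 4191 higher and 2334 to 3413 lower genes, day 4 against 0 held 3047 to 4110 and 1422 to 2339, day 7 against 0 held 1032 to 1444 and 677 to 2377, day 4 against 2 held 1216 to 2299 and 1310 to 2332, and day 7 against 4 held 458 to 1791 and 2048 to 3636. Genes that differed on any day numbered 8126 to 10596 then, and 6643 with the second index, the lowest of all settings, to 11407 with DESeq2, the highest. Lists called numbered 50.0 to 60.0; those that ended are given in the report. Others were gained, in the direction seen with all libraries (adjusted p from 0.0039 to 0.049). At day 2 against 0 they were of NF-κB targets without replicate 1 or 3 of either day, mural and Schwann markers without day 0 replicate 2 or 4 or day 2 replicate 2, and matrix without day 0 replicate 2 or day 2 replicate 4. At day 4 against 0 they were of ribosome assembly without day 0 replicate 4, interferon genes without day 4 replicate 3 or 4, and p53 and erythroid lists without day 4 replicate 3. At day 7 against 0 they were of ribosome assembly without day 0 replicate 2 or 4 or day 7 replicate 3 or 4, p53 genes without day 0 replicate 4 or day 7 replicate 3 or 4, quiescence without day 0 replicate 1 or 3 or day 7 replicate 3, myeloid markers without day 0 replicate 1 or 3 or day 7 replicate 2 or 3, and NF-κB targets without day 0 replicate 2. For day 4 against 2 they were of fibroadipogenic markers without day 2 replicate 1 or 3 or day 4 replicate 3, Schwann markers without day 2 replicate 1 or 3, chromatin genes without replicate 2 of either day or day 2 replicate 4, interferon genes without day 2 replicate 2 or day 4 replicate 4, matrix without day 2 replicate 4 and oxidative phosphorylation without day 4 replicate 2. From day 4 to 7 they were of endothelial markers without day 4 replicate 1, 3 or 4 or day 7 replicate 1 or 2. ATAC peaks numbered 4 to 101 higher and 9 to 94 lower, where a lone library of a genotype is assumed to vary like the other pair, and lists shared 54.7% to 65.9% of peaks within and 54.5% to 69.95% between genotypes, more within than between without wild-type replicate 2 and less without each of the others.

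Replicate numbers do not pair the animals: the correlation of deviations over 24 pairs ran from -0.43 to 0.30, with 4 above 0.1. With the number as a replicate block, 882 genes were lower for day 7 against 0, other counts were within 1.5 times, 8027 genes differed on any day, and 54 lists were called, of which 53 as without it. The blocked ATAC fit gave 15 higher and 19 lower peaks. Of 690.0 single gene results, 661 stayed on the same side of the threshold under the block, 27 lost and 2 gained a call.

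Of the 120 list tests, 53 were called, 5 with an estimated correlation, 44 with fry and 54 with DESeq2-type size factors. The second index as a covariate left 69 called, of which 47 as before, and turned myeloid markers down at day 4 and day 7 against 0 (adjusted p = 0.0041 and 0.0016, both uncalled and up before) and matrix genes at day 7 against 0 (adjusted p = 0.66). Calls gained there, besides those given in the report, were of matrix (down, adjusted p = 8.0e-04), chromatin (up, 0.042), endothelial (down, 0.041), fibroadipogenic (down, 0.008), mural (down, 0.01) and Schwann (down, 0.036) lists at day 2 against 0, of matrix (down, 3.7e-04), p53 (up, 0.0016) and ribosome assembly genes (up, 0.0016) at day 4 against 0, and of endothelial (down, 2.4e-04), p53 (up, 0.0029) and ribosome assembly genes (up, 0.0016) at day 7 against 0. Those for day 4 against 2 were of interferon (up, 0.0016), p53 (up, 0.014), fibroadipogenic (down, 0.0014) and Schwann lists (down, 0.014), and from day 4 to 7 of interferon genes (up, 0.014). Without the 4 marker-high libraries 58 were called, 44 as before, fibroadipogenic markers turned up at day 7 against 0 (adjusted p = 0.019) and endothelial markers at day 4 against 2 (adjusted p = 0.45). Calls gained in that setting, besides those in the report, were of quiescence at day 7 against 0 (down, adjusted p = 4.3e-05), of sarcomere (down, 0.033), endothelial (down, 0.036), mural (down, 0.018) and Schwann (down, 0.019) lists at day 2 against 0, of interferon (up, 1.0e-04) and chromatin genes (down, 3.4e-04) from day 2 to 4 and of Schwann markers from day 4 to 7 (up, 0.019). Among 690.0 single gene results in that setting, 614 kept their side of the threshold, 28 lost and 46 gained a call, and 2 that had no call before turned to a called rise: Msln at day 7 against 0 (log2 fold change 3.71) and Lgals3 at day 4 against 2 (0.87). With the second index 136 lost a call and 5 gained one, and with DESeq2 3 and 34. No other alternative run for them turned the direction of a called result among the genes and lists named.

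For ATAC, scaling by all tags gave 1 peak higher and 0 lower, and TMM over 10 kb bins 0 and 0. DESeq2 gave 9 and 12, and peaks found in all 4 libraries 2 and 5, with fewer peaks tested. Unfiltered lists shared 36.9% of peaks within and 39.3% between genotypes, and hold more peaks. Tests of list genes' promoters and of motifs in peaks were not run, for want of an mm9 reference. Most simulated 2-fold changes of genes were missed (14% recovered) but no alternative varied depth, so whether depth or the spread between libraries limits the calls was not tested.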

Other observations

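The tests of strain variants on both patterns and of sequencing batch were chosen after the values were seen, while those of other cells, copy number and other groupings were written before.

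Of 20 genes of cell death, 9 rose and 3 fell from day 0 to day 2, likewise adjusted over the list alone (adjusted p = 0.12). Mlkl, the effector of necroptosis, rose from 1.78 ± 0.838 to 22.7 ± 12.5 CPM (log2 fold change 3.69 ± 0.47, edgeR adjusted p = 1.3e-05), as did Casp8 (3.04 ± 0.44). At day 4, 8 were above day 0 and 3 below (9 and 3; adjusted p = 0.27). The p53 target Pmaip1 was at 36.8 ± 15.8 CPM against 2.73 ± 1.58 (3.73 ± 0.55, adjusted p = 7.5e-05). At day 7 the counts were 7 and 1 (8 and 1; adjusted p = 0.028, and adjusted p = 0.33 with an estimated correlation), the only contrast of the 5 in which the list was called, and not without the 4 libraries highest in other cells' markers (adjusted p = 0.091). From day 2 to 4, 1 rose and 2 fell (1 and 2; adjusted p = 0.36). From day 4 to 7, 2 fell (1; adjusted p = 0.56), where the median and mean lay below 0 (-0.04 and -0.06) and camera pointed up. In the p53 and senescence list of 15, 4 rose and 3 fell at day 2 (4 and 3; adjusted p = 0.59), 7 and 3 at day 4 (7 and 3; adjusted p = 0.11) and 2 and 1 at day 7 (4 and 1; adjusted p = 0.10). Ccng1, cyclin G1, rose from 67.5 ± 10.9 to 220.4 ± 47.6 CPM at day 4 (1.71 ± 0.22, adjusted p = 2.5e-05). In the steps between days, 3 rose and 1 fell from day 2 to 4 (4 and 1; adjusted p = 0.17) and 3 fell from day 4 to 7 (3; adjusted p = 0.57).

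Chromatin regulators went both ways. Of 20, 8 rose and 6 fell at day 2 (8 and 6 over the list alone; adjusted p = 0.64). The Polycomb methyltransferase Ezh2 rose from 10.99 ± 3.036 to 82.4 ± 25.9 CPM (log2 fold change 2.91 ± 0.28, adjusted p = 7.2e-07) as did the maintenance DNA methyltransferase Dnmt1 (3.38 ± 0.38). At day 4, 6 rose and 8 fell (6 and 9; adjusted p = 0.47), and at day 7, 5 rose (5; adjusted p = 0.0022, and adjusted p = 0.60 with an estimated correlation; adjusted p = 0.055 without the 4 marker-high libraries). From day 2 to 4, 1 rose and 6 fell (1 and 6; adjusted p = 0.08), and 10 rose and 3 fell from day 4 to 7 (11 and 3; adjusted p = 1.6e-05, and adjusted p = 0.39 with an estimated correlation), among them Tet2 (1.50 ± 0.31) and Suz12 (2.04 ± 0.46). Interferon response genes rose at day 4 in 7 of 20 without a call for the list (7 and 1 lower over the list alone; adjusted p = 0.12), Isg15 going from 4.552 ± 4.398 to 33.32 ± 20.89 CPM (2.90 ± 0.81, adjusted p = 0.01, lost with the second index as a covariate). Without the 4 libraries highest in other cells' markers this list was called up (adjusted p = 0.0064). In the other contrasts 2 rose at day 2 (1; adjusted p = 0.67), 2 at day 7 (0; adjusted p = 0.0076, and adjusted p = 0.74 with an estimated correlation). From day 2 to 4, 3 rose and 1 fell (3 and 1; adjusted p = 0.18) and 1 rose from day 4 to 7 (1; adjusted p = 0.70), where the median was -0.45 and camera pointed up. Of 16 NF-κB components, the list that holds Ikbkg, 3 rose at day 2, 2 rose and 3 fell at day 4 and none passed at day 7 (the same counts over the list alone; adjusted p = 0.84, 0.62 and 0.62). Nfkb2 rose from 37.1 ± 10.8 to 139 ± 40.4 CPM at day 2 (1.90 ± 0.27, adjusted p = 3.7e-05). The medians at days 2 and 7 were -0.11 and 0.05 with means of 0.12 and 0.05. From day 2 to 4, 1 rose and 1 fell (adjusted p = 0.35), and from day 4 to 7, 1 rose and 2 fell (adjusted p = 0.22), likewise over the list alone.

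The predicted gene Gm8210, chosen after its values were seen and with the same values as Gm13841, so that reads of both are uncertain, was under 1 CPM in 5 libraries, day 2 replicates 2 and 4 (0.212 and 0.236), day 4 replicates 3 and 4 (0.0956 and 0) and day 7 replicate 3 (0.054), and at 17.7 to 129 CPM in the other 7 libraries of these days. RNA from other cells that dilutes satellite cell RNA is excluded as the whole cause, since the summed myogenic genes of these libraries were 0.50, 1.14 and 0.943 of those of the others of days 2, 4 and 7, and so is the sequencing batch, as 2 of the 3 second index sets hold both kinds of library within a day. A strain variant may be the source, though any other difference between these animals predicts the same: 5 further genes lay at least 2-fold apart between the same libraries, more than in any of the other choices of libraries of these days (highest 3, 1 of 144.0). Whether these libraries carry the genotype on their label stays open and bears on each RNA comparison. They held the highest Ikbkg of their day, as given in the report. Day 0 libraries held 24.7 to 41.4 CPM of Ikbkg beside 20.5 to 32.3 of Gm8210. No wild-type RNA was used here to read either against. Without the 5 libraries day 4 keeps replicates 1 and 2. Its contrasts then called fewer genes (208 higher and 260 lower for day 7 against 4). More passed for days 2 and 7 against 0 (3612 and 3606, 1932 and 1590).

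Of the 31 ATAC peaks that differed between genotypes, 12 lay on chromosome 9, which holds 3871 of the 70013 tested peaks (5.53%). A whole-chromosome copy change in all cells is excluded. Its share of tags outside peaks was 0.937 of wild type in NEMO KO (4.54% and 4.84% against 5.00% and 5.00%), within preset bounds. A partial change was not tested. At most 3 of the 31 smallest p lay on chromosome 9 in the other 2 splits, too few splits to exclude peaks that vary in any grouping. Of the next 100 peaks by p, 24 also lay on chromosome 9, but these come from the same fit and any difference between the genotypes on that chromosome predicts them, so a stretch of another strain's sequence and an effect of the genotype itself cannot be told apart. No strain or bred allele on that chromosome is named in the sources used here, on X, where Ikbkg lies, 1 of 1400.0 tested peaks was called, and with 2 against 2 libraries the splits are too few to exclude chance: the real split called 31 peaks and the other splits 0, with 5224 and 1951 peaks at unadjusted p under 0.05 against 2339 in the real split (edgeR).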
